A study of Mus musculus with 8 samples.

How the data were processed

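ATAC-seq peak lists of 8 libraries were used: HC800a8-1 and HC569a8-18 cells, control and DOX, 2 libraries each. Grouping followed the sample labels, in which DOX cells are Hnf4a-positive and control cells Hnf4a-negative. Per the submitters' processing notes, reads were mapped with Bowtie 1.1.2 to mm10. Per the file headers, peaks were called with MACS2 2.1.0.20140616 on each library alone, without an input control, at a p cutoff of 1e-10, with a band width of 300 bp, a model fold range of 15 to 100, a regional background range of 10 kb and 1 tag kept per position. No Tn5 shift or extension option was in the command line per the file headers. Read trimming, mapping settings and filters before peak calling were not given in the sources used here.

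The deposited tables gave positions (1-based, mm10), the signal as fragment pileup coverage at the summit, the −log10 p-value and −log10 q-value of that pileup against the local background of the same library, and the fold enrichment ratio over that background, all computed by the authors with MACS2 per the file headers. The score and the fold per peak are therefore the authors' own values. Folds were averaged over the libraries that listed a region and were not compared between treatments, because a region absent from a list has no deposited fold. Per the file headers, total tags ranged from 8.78 to 28.4 M and tags kept after removal of redundant ones from 2.11 to 15.5 M, with 20% to 82% redundant. Peaks on the mitochondrial genome, 7 to 12 per library, were left out.

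The share of covered bases that 2 lists had in common (Jaccard index) was computed with bedtools 2.31.1. Peaks of all lists were merged into 31021 regions wherever they overlapped by at least 1 bp. Of these, 11594 were in a single list. A region was called gained in both lines when all 4 DOX and no control libraries listed it, and lost when all 4 control and no DOX libraries did. In a single line, a gained region was in both DOX and neither control list, and a lost region the reverse. Counts were compared with 1000 randomisations that swapped peaks between the libraries of a line while list lengths and region totals were kept. Overlap between the lines was compared with independent sets, with Fisher's exact test among regions in 2 of the 4 lists of each line, and with the 36 assignments of libraries within lines. Means of libraries were compared by 2-sided exact permutation of 4 against 4 libraries (70 assignments, smallest p 0.0286), with Benjamini-Hochberg adjustment over gene lists.

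Each region was linked to the nearest protein-coding gene interval within 100 kb, of 21887 intervals in the RefSeq table for GRCm38.p6, which has the coordinates of mm10. Distances, and whether a region lay inside a gene, were taken from the midpoint of the region. The plan named the nearest transcription start and regions around it. The table holds gene intervals without strand, so strand, transcription starts and exons were not used here, and a distance of 1 kb from either gene end took the place of the promoter. A reference genome was not used here, so 3 planned motif results were not run. Gene lists were epithelial adhesion, classical and basal-like pancreatic cancer, mesenchymal, Six1, Eya and mesodermal factors, HNF4A targets of liver and intestine, endoderm and pancreas factors, acinar enzymes, endocrine, AP-1 and inflammation, immune, endothelial and fibroblast markers, and housekeeping genes. Of 330 listed symbols, 329 were matched, 2 of them by an older name, and 202 had a region. The number of members with a gained or lost region was compared with 10000 random lists of the same size matched on the number of regions per gene, a permutation of gene labels.

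Named genes followed a fixed rule: always Hnf4a, then the 12 genes with the most gained and the 12 with the most lost regions in both lines, ties going to the region with the highest worst within-list percentile of the authors' score, and up to 4 members of each list per direction. Comparisons, tests, lists, naming rule and the alternatives (the stronger 50% of each list, lists of equal length, 50% cover, 1 kb bins, other link distances, each library left out, replicate block) were chosen before the data were examined. Gene intervals in place of transcription starts, and a few alternatives named with their effects, were chosen later. The counts were tested on simulated data: with no planted difference in 31000 regions, 1 of 20 simulations gave a p under 0.05 for gained and 0 of 20 for lost regions, and with 200 planted regions 20 of 20 did, with 75.7% recovered. That share was set by the listing chances given to the planted regions, so it does not measure sensitivity for real regions. The simulated libraries shared a common strength per region and had no structure by line, replicate or redundant rate. The error rate with such structure, which the real libraries have, was therefore not tested. Of 400 simulated lists of 20 genes, 1.25% of unrelated and 70% of enriched ones had a p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.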

Results

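Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 2 mouse pancreatic ductal adenocarcinoma cell lines of mixed strain background, HC800a8-1 and HC569a8-18. Per the labels, the cells were cultured for 7 days with vehicle or with doxycycline at 1 mg/ml, and 250000 nuclei entered each library. The dose is high for cell culture, and its unit was taken as the labels give it. Control cells were labelled negative for Hnf4a, a nuclear receptor that drives gene expression in liver, gut and pancreas, and doxycycline-treated (DOX) cells were labelled positive. The design asks how chromatin differs between Hnf4a-negative cancer cells and cells of the same line in which the factor was restored. Each of the 4 groups held 2 libraries, and the number in brackets in the titles, shared by all libraries of one replicate number, may mark a batch. The labels do not say that the replicates came from separate cultures. P-values from permutations of libraries therefore measure the spread between these libraries, which may be technical. Those from swapped lists, matched random gene lists and Fisher's exact tests take regions or genes as units and do not measure that spread.

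The peak lists of one treatment differed in length as much as those of different treatments. HC800a8-1 control libraries held 24484 and 13030 peaks, HC800a8-1 DOX libraries 8485 and 8926, HC569a8-18 control libraries 5083 and 13347, and HC569a8-18 DOX libraries 18554 and 6960. The mean was 10731 ± 5283 peaks in DOX and 13986 ± 7975 in control libraries (SD, n = 4 each), with no difference past the spread in a 2-sided exact permutation test (p = 0.514). Control libraries had the more redundant tags, 70.5% ± 12.8 against 37.8% ± 14.4 in DOX libraries (SD, n = 4 each; exact permutation p = 0.0286). They also gave more peaks per 1000 tags kept, 2.85 ± 1.31 against 1.29 ± 0.181 (SD, n = 4 each; exact permutation p = 0.0286), where 0.0286 is the smallest p that 4 against 4 libraries allow. Tags kept were 5.17 and 5.21 M in HC800a8-1 control, 6.94 and 5.73 M in HC800a8-1 DOX, 2.11 and 7.65 M in HC569a8-18 control, and 15.5 and 5.89 M in HC569a8-18 DOX libraries (M for mega). A region missing from a list was therefore only below the authors' cutoff in that library, which is not evidence of closed chromatin.

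**Figure D1:**
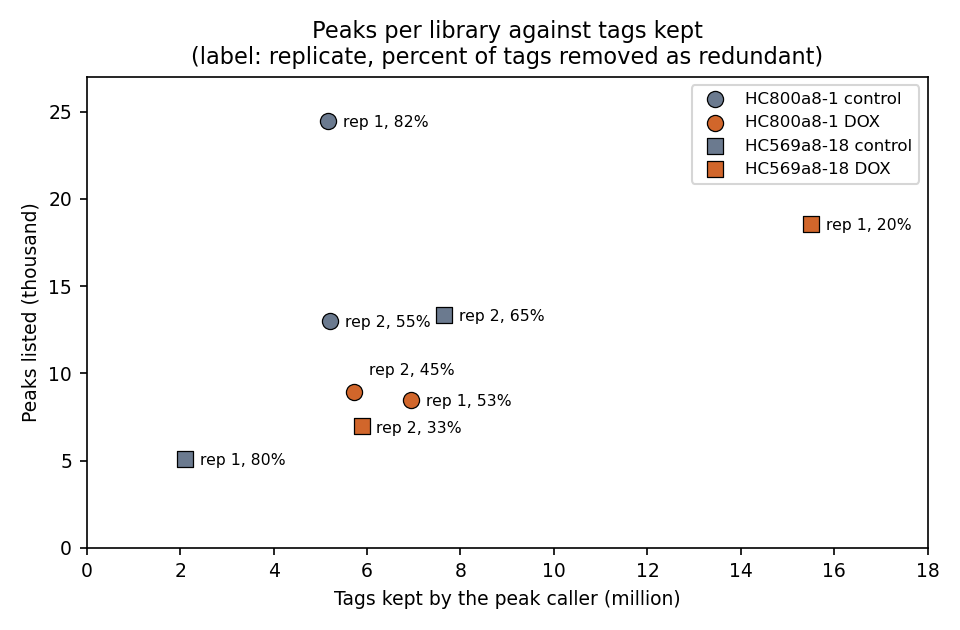
Peaks listed (in units of 1000, vertical axis) against tags kept by the peak caller (M, horizontal axis) for each of the 8 libraries, circles for HC800a8-1 and squares for HC569a8-18, grey for control and orange for DOX, labelled with the replicate and the percent of tags removed as redundant. HC800a8-1 control replicate 1 listed 24484 peaks from 5.17 M tags, whereas HC569a8-18 DOX replicate 1 listed 18554 from 15.5 M.

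At the Hnf4a gene itself (chromosome 2, 163506811 to 163572907, mm10), DOX libraries of both lines listed accessible regions that no control library held. The region at 163551550 to 163551762 was in 4 of 4 DOX and 0 of 4 control lists, at 18.1 ± 2.96 times the local background (SD, n = 4). The region at 163558945 to 163559093 was likewise in 4 of 4 DOX and 0 of 4 control lists, at 13 ± 1.17 times the background (SD, n = 4). Further DOX-only regions lay at 163566133 to 163566330 (3 DOX lists), at 163564171 to 163564290 and 163568904 to 163569018 (2 DOX lists each), and at 163515637 to 163515877 (1 DOX list). By contrast, the region over the lower-numbered end of the gene, 163506681 to 163506924, was in 2 control lists and 1 DOX list. Of 8 regions overlapping Hnf4a, 6 were listed only in DOX and 1 only in control libraries. DOX libraries held 4.25 ± 2.22 peaks over the gene and control libraries 0.75 ± 0.957 (SD, n = 4 each; exact permutation p = 0.0571). Positions relative to exons were not analysed here, so reads from an introduced Hnf4a coding sequence were not separated from those of the gene's own locus.

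**Figure D2:**
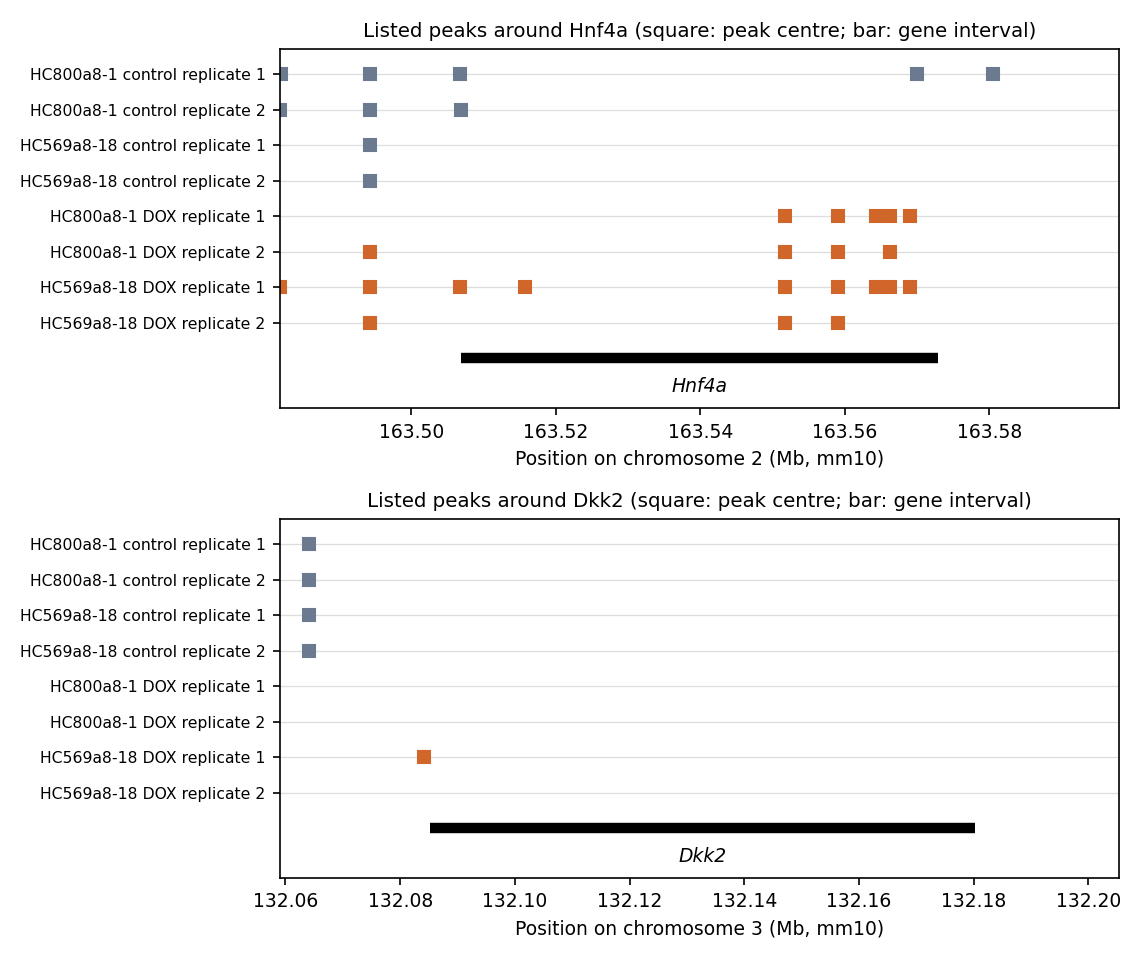
Peaks listed by each library (rows; squares at peak centres, orange for DOX and grey for control) around Hnf4a on chromosome 2 and Dkk2 on chromosome 3, with position in Mb (mm10) and the gene interval as a bar. Inside Hnf4a, 2 regions were in all 4 DOX lists and no control list, and near Dkk2 the region at 132064064 was in all 4 control lists and no DOX list.

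Across the genome, 159 regions were gained in both lines, meaning that they were listed in all 4 DOX and no control library. They lay mostly away from gene ends: 8 of them (5.03%) fell within 1 kb of either end of a protein-coding gene, against 28.4% of all 31021 merged regions and 56.4% of the 2901 regions in all 8 lists. A low share was not particular to them. It was 18.6% for regions in all HC800a8-1 and no HC569a8-18 lists, and 7.14% for the reverse. The 159 gained regions were linked to 149 genes, of which only Hnf4a had 2 such regions. Among the named genes, Vil1, which encodes the brush-border protein villin, gained a region inside the gene (chromosome 1, 74411904 to 74412180) at 12.7 ± 2.1 times the background (SD, n = 4). Proc, the gene of the liver-made anticoagulant protein C, gained a region just outside the gene, its midpoint 0.118 kb away (chromosome 18, 32139592 to 32139784). It stood at 9.94 ± 0.984 times the background (SD, n = 4).

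Ocln, which encodes the tight-junction protein occludin, gained a region inside the gene (chromosome 13, 100532945 to 100533268; 9.91 ± 2.54 times the background, SD, n = 4). Anxa10, an annexin gene placed on the list of classical-subtype pancreatic cancer markers, gained a region inside the gene (chromosome 8, 62119520 to 62119843; 8.57 ± 0.756, SD, n = 4). The VEGF receptor gene Kdr was the nearest gene to a gained region 9.96 kb away (chromosome 5, 75922701 to 75923035; 14.4 ± 1.12, SD, n = 4). Jun, an AP-1 subunit gene, was the nearest gene to a gained region as far as 89.2 kb away (chromosome 4, 95141332 to 95141548; 10.6 ± 2.21, SD, n = 4). Maml2, which encodes a Notch coactivator, gained a region inside the gene (chromosome 9, 13681753 to 13681973; 15.6 ± 1.29, SD, n = 4), and so did Arhgef28, a Rho guanine-exchange factor gene (chromosome 13, 97976715 to 97977060; 14.3 ± 0.773, SD, n = 4).

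The other genes with the highest-ranked gained regions were Smim1, Tmem220, Ccdc93, Krt84, Gpr85, Sel1l3, 3110040M04Rik and Mfsd13b, with mean folds over the background from 11.7 at 3110040M04Rik to 15.9 at Gpr85. The regions of Smim1, Tmem220, Ccdc93, Sel1l3 and Mfsd13b lay inside the genes. Those of Krt84, a hair keratin gene, and Gpr85, an orphan receptor gene, lay 2.11 and 17.6 kb away, and that of 3110040M04Rik 57.8 kb away. When every list was limited to its 5083 strongest peaks, the regions of these genes, of Maml2, Kdr and Arhgef28, and the Hnf4a region at 163551550 were still in all 4 DOX and no control lists, which follows largely from their having been named by rank within the lists. The Hnf4a region at 163558945 was then in 3 DOX lists. The Vil1 region was also in 3, Jun in 2, Ocln in 1, and Anxa10 and Proc in 0, with no control list holding any of them.

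The count of 159 gained regions compared with 0.627 ± 0.807 (mean ± SD of 1000 draws; highest 6) when peaks were swapped between libraries with each list's length and each region's total kept within a line (1-sided permutation p = 0.001, the smallest that 1000 draws give). With lists of equal length, 127 regions met the rule, against 11.1 on average in swapped lists. Of the 159, 49 (30.8%) were among them. The rest of the 127 missed the rule on the lists as deposited because at least 1 control list held them there. Within replicate number 1 alone, 663 regions were listed in both DOX and no control libraries, and within replicate number 2 alone 299. At equal list lengths these counts were 464 and 392. The count was 71 with the stronger 50% of each list, which included 42 of the 159 (26.4%), and it was 240 without HC800a8-1 control replicate 1 and 350 without HC569a8-18 DOX replicate 2. Of the 35 splits of the libraries into 4 and 4, 1 other gave a larger count, 868, and it set the 4 longest lists against the 4 shortest.

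**Figure D3:**
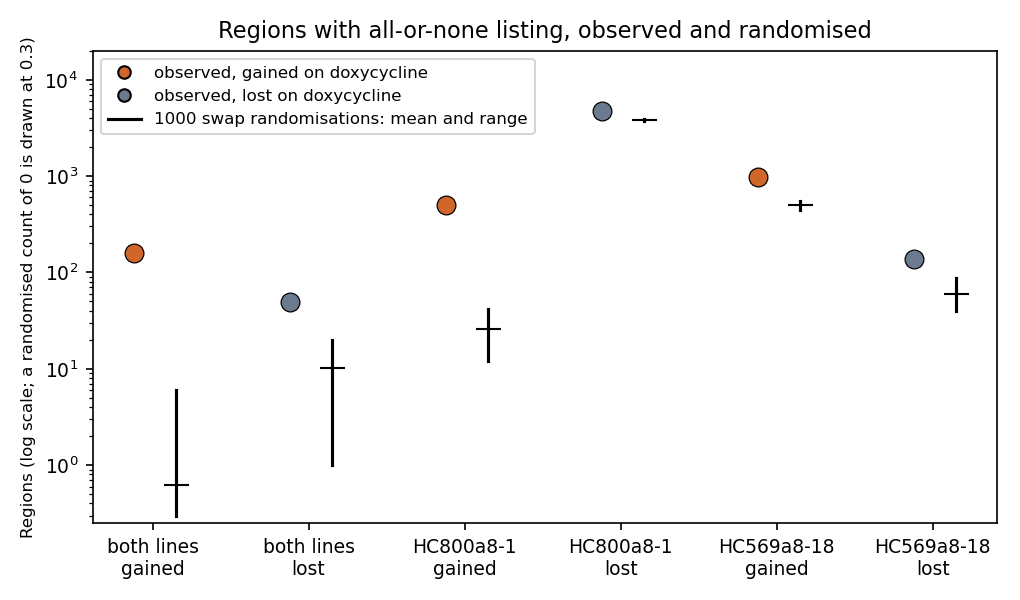
Number of regions (log scale) gained (orange) or lost (grey) on doxycycline in both lines and in each line, beside the mean (tick) and range (bar) of 1000 randomisations that kept list lengths and region totals within each line. The 159 regions gained in both lines compare with at most 6 in the randomised lists, and the 4705 lost in HC800a8-1 with 3812 on average.

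**Figure D4:**
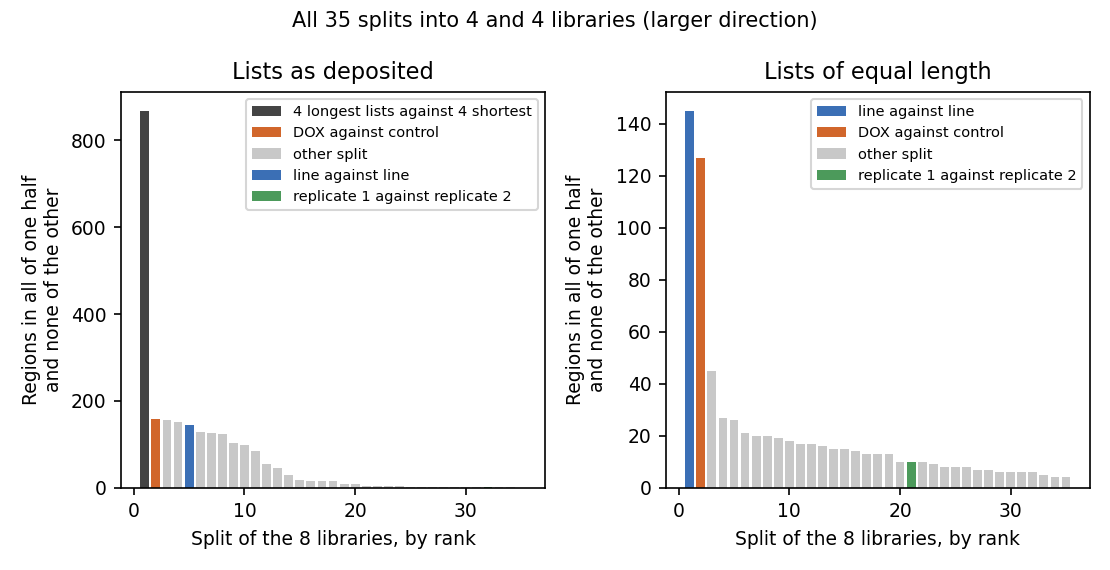
Number of regions listed in all libraries of one set of 4 and in none of the other 4 (vertical axis; the larger direction), for each of the 35 splits of the 8 libraries ranked along the horizontal axis, with lists as deposited (left) and of equal length (right). DOX against control ranked below 1 other split in each panel, at 159 and 127 regions.

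In the opposite direction, 49 regions were lost in both lines, that is, listed in all 4 control and no DOX library. They were linked to 44 genes, each with a single such region, and 26.5% lay within 1 kb of a gene end, a larger share than the 5.03% of gained regions (Fisher's exact test over regions, odds ratio 0.147, p = 7.78e-05; regions are not independent replicates). Dkk2, a gene of a secreted Wnt modulator, lost a region 21.1 kb from the gene (chromosome 3, 132064064 to 132064290), which control libraries held at 14.1 ± 4.11 times the background (SD, n = 4). Flt1, the VEGF receptor 1 gene, lost a region 60.6 kb away (chromosome 5, 147786939 to 147787209; 12 ± 3.13, SD, n = 4), while Kdr on the same chromosome gained its region. Serpina3n, a serine protease inhibitor gene, lost a region 1.48 kb away (chromosome 12, 104415658 to 104415974; 11.9 ± 2.03, SD, n = 4).

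Regions inside the genes were lost at Rbms3, which encodes an RNA-binding protein (chromosome 9, 117134106 to 117134365; 14.3 ± 4.33, SD, n = 4), at the adaptor gene Fyb (chromosome 15, 6540087 to 6540299; 14 ± 3.86, SD, n = 4) and at Ndrg2 (chromosome 14, 51913313 to 51913564; 11.6 ± 1.73, SD, n = 4). Lrrcc1 and Tacc2, both genes of centrosomal proteins, and Iffo2 also lost a region inside the gene, at 12.5 ± 1.67, 9.9 ± 1.69 and 9.55 ± 0.539 times the background (SD, n = 4 each). Tmem211 lost a region that overlapped the gene end, with its midpoint 0.056 kb outside. Regions were lost 8.2 kb from 4930578I06Rik, 12.7 kb from Prdm15 and 19.1 kb from Gm536. The 49 lost regions compared with 10.2 ± 3.07 in swapped lists (mean ± SD of 1000 draws; highest 20; 1-sided permutation p = 0.001, the smallest possible). With equal list lengths 50 regions met the rule, but only 2 of the 49 (4.08%) were among them, and none of the named lost regions kept its place in all 4 control lists. The count was 28 with the stronger 50% of each list, which included 1 of the 49, 624 without HC569a8-18 control replicate 1 and 268 without HC569a8-18 DOX replicate 1. It was 108 within replicate number 1 and 2145 within replicate number 2, where both control lists were the longer ones. At equal list lengths it was 362 and 344.

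In HC800a8-1, 496 regions were gained, meaning in both DOX and neither control list of the line, and 4705 were lost in the reverse sense. The list of known HNF4A target genes of liver and intestine had 3 of 23 members with a gained region, Apob, Proc and Vil1, against 0.502 in matched random lists (permutation p = 0.0222, adjusted p = 0.311 over 14 lists). The Apob region, 57.5 kb from this apolipoprotein B gene (chromosome 12, 7920039 to 7920188), was in 3 DOX lists at 8.39 ± 1.02 times the background (SD, n = 3), whereas another region 54.1 kb from Apob (chromosome 12, 8070840 to 8071059) was lost in the line. Pecam1, an endothelial adhesion gene, gained a region inside the gene (chromosome 11, 106707960 to 106708182; 9.46 ± 0.722, SD, n = 3). Ywhaz, a housekeeping gene, had both a gained region inside the gene and 2 lost regions outside it.

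Lost regions of HC800a8-1 reached members of all 14 fixed lists, mostly in numbers near those of matched random lists. Mesenchymal genes had 13 of 21 members with a lost region against 8.73 in matched random lists (permutation p = 0.077, adjusted p = 0.539), among them the transcription factor gene Snai1 and the collagen gene Col5a1 with 3 each, and Tgfbi and Itga5 with 2 each. Endocrine genes had 4 of 7 members against 1.06 (permutation p = 0.0218, adjusted p = 0.305), namely Mafb, Chgb, Neurog3 and Neurod1. Endoderm and pancreas transcription factor genes had 11 of 20 members against 7.97 (permutation adjusted p = 0.854), including Gata6 and Ehf with 3 lost regions each and Hhex and Foxa2 with 2 each. The AP-1 and inflammation list had 11 of 21 members against 8.29, including Jun with 3 lost regions, Ptgs2, Il33 and Atf3. Eya2, a transcriptional cofactor gene, had 4 lost regions inside the gene. Six1 had 1 that overlapped the gene end, with its midpoint 0.041 kb outside. Eya2 and Six1 were the 2 of 13 members of the Six1, Eya and mesodermal list with a lost region. Basal-like subtype genes had 7 of 15 members against 5.24, and classical-subtype genes 4 of 14 against 4.11. Epithelial adhesion genes had 3 of 14 members with a lost region, Cdh1, Cldn4 and Tjp1, against 4.97, and HNF4A targets 4 of 23 against 4.75. Endothelial markers had 4 of 12 members (Flt1 with 5 lost regions), fibroblast markers 3 of 7, acinar enzymes 2 of 6, immune markers 2 of 6 and housekeeping genes 7 of 23, with adjusted p from 0.854 to 1.

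The 496 gained regions of HC800a8-1 compared with 25.8 in swapped lists and the 4705 lost with 3812 (1-sided permutation p = 0.001 each, the smallest possible). These swaps took regions as units, and 2 against 2 libraries cannot reach the 0.05 threshold in a permutation of the libraries. Within replicate number 1 the line gained 961 and lost 16597 regions, and within replicate number 2 it gained 1755 and lost 5924. At equal list lengths these counts were 1986 and 2028, and 1817 and 1846. Its control lists were the longer ones, and with lists of equal length the line gained 700 and lost 691 regions, against 345 and 360 in swapped lists. Gained regions numbered 1005 without control replicate 1, 807 without DOX replicate 1 and 948 without DOX replicate 2, and lost regions 14704 without control replicate 2.

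In HC569a8-18, 970 regions were gained and 139 lost. Epithelial adhesion genes had 3 of 14 members with a gained region, Ocln, Tjp1 and Epcam, against 1.3 in matched random lists (permutation p = 0.258). The Tjp1 region inside this tight-junction scaffold gene (chromosome 7, 65468298 to 65468467) was in 3 DOX lists at 8.56 ± 2.27 times the background (SD, n = 3), and a different region inside Tjp1 (chromosome 7, 65410663 to 65410842) was lost in HC800a8-1. HNF4A target genes had 3 of 23 members with a gained region, Proc, Vil1 and Mttp, against 0.955 (permutation p = 0.121). The Mttp region lay inside this lipid transfer protein gene (chromosome 3, 138096584 to 138096841) and was in both DOX lists of the line only, at 8.44 ± 1.13 times the background (SD, n = 2). Mesenchymal genes had 4 of 21 members with a gained region, Zeb2, Col5a1, Thy1 and Tgfbi, against 2.41 (permutation p = 0.424). The regions of Zeb2, Thy1 and Tgfbi were also in both control lists of HC800a8-1. Gata6, with 3 lost regions in HC800a8-1, had a gained region 15.4 kb away in HC569a8-18 (chromosome 18, 11100952 to 11101148), which 1 HC800a8-1 control list also held. Klf4, Plaur, Csf1r and Cdh5 each gained 1 region, that of Plaur also in both HC800a8-1 control lists. Of the fixed lists only Meox2 and Flt1 lost 1.

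The 970 gained regions of HC569a8-18 compared with 503 in swapped lists and the 139 lost with 59.8 (1-sided permutation p = 0.001 each, the smallest possible). As in HC800a8-1, the swaps took regions as units, and 2 against 2 libraries cannot reach 0.05 when libraries are permuted. Within replicate number 1 the line gained 13474 and lost 180 regions, and within replicate number 2 it gained 1049 and lost 7329. At equal list lengths these counts were 2036 and 1977, and 1849 and 1852. With lists of equal length the line gained 618 and lost 568 regions, against 326 and 315. Gained regions numbered 7629 without DOX replicate 2 and 2983 without control replicate 2, and lost regions 2475 without control replicate 1 and 1161 without DOX replicate 1.

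The lines gained the same regions more often than independent sets would. Of the 496 regions gained in HC800a8-1, 159 were also gained in HC569a8-18, against 15.5 for independent sets among the 31021 regions. Among the 1409 regions in exactly 2 of the 4 lists of each line, 30.2 would be expected (Fisher's exact test over regions, odds ratio 196, p = 7.29e-129). Regions gained in HC800a8-1 were in more DOX than control lists of HC569a8-18 in 381 cases and in more control lists in 3. Of those 381, 159 were in both DOX and neither control list of HC569a8-18. The 970 regions gained in HC569a8-18 were in more DOX lists of HC800a8-1 in 338 cases and in more control lists in 165 (17.0%). These counts are for lists as deposited, which differed in length. HC569a8-18 DOX replicate 1 listed 18554 peaks and HC569a8-18 control replicate 1 listed 5083. For lost regions the overlap of 49 compared with 21.1 for independent sets and, among the same 1409 regions, with 36.1 (odds ratio 10.6, Fisher's exact p = 5.82e-06). Both Fisher tests took regions as independent replicates, which they are not, so their p-values do not measure the spread between libraries. The 4705 regions lost in HC800a8-1 were in more control lists of HC569a8-18 in 850 cases and in more DOX lists in 861, and the 139 lost in HC569a8-18 were in more control lists of HC800a8-1 in 92 cases and in more DOX lists in 2, with lists of unequal length in each case. Over the 36 ways to assign 2 of 4 libraries in each line, 2 gave an overlap at least as large as the gained one and 5 one as large as the lost one.

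Of the fixed gene groups, those with a member among the 159 regions gained in both lines were HNF4A targets (2 of 23, Proc and Vil1), epithelial adhesion (1 of 14, Ocln), classical-subtype genes (1 of 14, Anxa10), AP-1 and inflammation (1 of 21, Jun) and endothelial markers (1 of 12, Kdr). The HNF4A target count compared with 0.157 in matched random lists (permutation p = 0.0228, adjusted p = 0.319), and both regions left it with the stronger 50% of each list or with equal lengths. No member of the basal-like (15 with a region), mesenchymal (21), Six1, Eya and mesodermal (13), endoderm and pancreas factor (20), acinar (6), endocrine (7), immune (6), fibroblast (7) or housekeeping (23) lists was gained in both lines, and Flt1 was the single member lost in both. Of 84 set tests over the gained and lost sets, 0 passed after Benjamini-Hochberg adjustment over the lists and 3 had an unadjusted p under the 0.05 threshold.

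The share of each library's peaks near HNF4A target genes was 0.138% ± 0.0153 in DOX and 0.101% ± 0.0114 in control libraries (SD, n = 4 each; 2-sided exact permutation p = 0.0286, adjusted p = 0.133). Shares near the Six1, Eya and mesodermal genes, 0.0577% ± 0.00944 in DOX against 0.0884% ± 0.0118 in control libraries, and near endocrine genes, 0.0134% ± 0.00231 against 0.037% ± 0.0072, differed the other way with the same exact p of 0.0286 and adjusted p of 0.133 (n = 4 each). Epithelial adhesion genes took 0.148% ± 0.0244 of DOX and 0.103% ± 0.024 of control peaks (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.2). Thus 0 of 14 lists passed after adjustment and 3 before it, and with lists of equal length the exact p of these 3 were 1 for HNF4A targets, 0.4 for the Six1, Eya and mesodermal list and 1 for endocrine genes. Mesenchymal genes took 0.177% ± 0.025 of DOX and 0.215% ± 0.101 of control peaks (SD, n = 4 each; exact permutation p = 0.457). The remaining 9 lists had exact permutation p from 0.0857 for acinar enzymes to 1 for classical-subtype genes. Peaks within 1 kb of a gene end were 39.7% ± 6.48 of DOX and 41.2% ± 5.48 of control lists (SD, n = 4 each; exact permutation p = 0.629).

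With lists of equal length, replicates of a group resembled each other most. At that length, replicate pairs shared 70.5% of their regions on average, libraries of the same line and the other treatment 61.5%, libraries of the other line and the same treatment 59.8%, and libraries that differed in both 55.3%. On the lists as deposited, which differ in length, the Jaccard index of covered bases averaged 0.417 for replicates. It averaged 0.337, 0.35 and 0.333 for the other kinds of pair in that order. It was 0.297 between the HC569a8-18 control replicates, with lists of 5083 and 13347 peaks. Between the control replicates 2 of HC800a8-1 and HC569a8-18 it was 0.483. At equal length the HC569a8-18 control replicates shared 73.1% of their regions and the pair across lines 63.5%. No test was made across pairs because they share libraries.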

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

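The tests of redundant rate, of doxycycline itself, of an introduced Hnf4a copy and of clustering, and the expectations set for the splits and randomised lists, were chosen after the results were seen.

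HC569a8-18 DOX replicate 1 stood apart from the other DOX libraries by the gap test for single libraries, with 18554 peaks and 15.5 M tags kept. These were 2 of 36 groups tested over 18 measures, and chance alone marks about 1 in 20. The share of peaks near classical-subtype genes moved in opposite directions, by -0.0184 percentage points in HC800a8-1 and by 0.0199 in HC569a8-18 on doxycycline, with every library of a line on its side. That difference between the lines was not tested.

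The 159 regions gained in both lines, Hnf4a, Vil1, Proc and Kdr among them, exceeded the highest count of 6 in swapped lists. The swaps did not use peak strength, but 127 regions met the rule at equal lengths, 49 of the 159 among them. This argues against list length as the whole cause of the count. The rest of the 127 were each held by a control list as deposited, so they were not regions that control lists lacked. Redundancy differed between treatments and stays open. Between the HC800a8-1 libraries of 53% and 55% redundant tags, 88.1% of the HC569a8-18 gained regions that 1 of the pair listed, at equal lengths, were in the DOX library, but this was a single DOX and a single control library of different replicate numbers, and 49 of the 159 regions met the rule at equal lengths. Among the 35 splits, 2 had a side reaching 159, the other at 868 with the 4 longest lists together, and at equal lengths 2 reached 127, so their number did not exclude chance, although the other, at 145, was the split between the lines, a structure of the samples, and the next highest was 45. Doxycycline itself cannot be told apart from Hnf4a, since 0 libraries came from treated cells labelled Hnf4a-negative, and restored Hnf4a, the difference the design names, stays open and untested.

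The 49 regions lost in both lines, among them those near Dkk2, Flt1 and Serpina3n, exceeded the highest of 20 in swapped lists. The swaps kept region totals but did not use peak strength, and only 2 of the 49 met the rule at equal lengths. List length therefore stays open as the cause for most of these regions. Of HC569a8-18 lost regions that 1 of the same HC800a8-1 pair listed, at equal lengths, 79.1% were in the control library, but this rests on the same single libraries, and only 2 of the 49 met the rule at equal lengths, so redundancy stays open. Of the 35 splits, 12 had a side of 49 or more, and 2 had both sides that large, the other being the split between the lines with a smaller side of 98, so their number did not exclude chance, and at equal lengths 50 regions were lost against at most 45 on a side of any other split but that between the lines. A lower yield of peaks in DOX libraries, which gave 1.29 peaks per 1000 tags kept against 2.85, stays open, as does an effect of doxycycline itself.

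The DOX-only regions inside Hnf4a may come from the gene's own locus opening or from reads of an introduced coding sequence. All 6 lay inside the gene and 0 in its flanks, and by length alone this had a probability of 0.058. Exon positions were not used, so the introduced copy and the native locus cannot be told apart. Clustering by chance was less able to produce the pattern, because 0 other genes had as many as the 5 regions of Hnf4a in at least 2 DOX and no control lists, among 940 genes with any. The next gene had 4, and genes were not matched on length or number of regions.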

How the results depend on the processing

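The replicate block, the stricter and equal-length lists and the libraries left out were chosen before the data were examined; leaving out the 2 libraries of highest redundant rate, and linking by the nearest gene end, were chosen after seeing the data. The alternatives for the 3 motif results were not run, because no genome was used. With the stronger 50% of each list, 71 regions were gained and 28 lost in both lines, HC800a8-1 gained 239 and lost 2291, and HC569a8-18 gained 573. Shorter lists hold fewer regions by construction. With lists of equal length, HC800a8-1 lost 691 regions, HC569a8-18 gained 618 and HC569a8-18 lost 568, so the imbalance between directions in each line came with the list lengths. Without the 2 libraries of highest redundant rate, 243 regions were gained (16 in swapped lists) and 661 lost (283). HNF4A targets with a region gained in both lines fell from 2 to 0 with stricter and to 0 with equal-length lists. Regions gained in both lines ranged from 159 to 350 when 1 library was left out (240 without HC800a8-1 control replicate 1, 350 without HC569a8-18 DOX replicate 2), and regions lost in both from 49 to 624 (624 without HC569a8-18 control replicate 1, 268 without HC569a8-18 DOX replicate 1). HC800a8-1 gained 504 to 1005 (1005 without control replicate 1, 807 without DOX replicate 1, 948 without DOX replicate 2) and lost 5030 to 14704 (14704 without control replicate 2). HC569a8-18 gained 989 to 7629 (7629 without DOX replicate 2, 2983 without control replicate 2) and lost 145 to 2475 (2475 without control replicate 1, 1161 without DOX replicate 1). A rule over fewer libraries is easier to meet, so these counts rose by construction, and the cause of their unequal rise was not tested. The DOX minus control share of peaks near gene ends ranged from -4.13 to 1.58 and changed sign without HC569a8-18 control replicate 1 (0.0504) and without HC569a8-18 DOX replicate 1 (1.58); the cause was not tested. With 1 library left out, the number of gene lists past adjustment was 0 to 0 for shares and for enrichment. For shares little else was possible, because with a smallest exact p of 0.0286 most of the 14 lists would have to tie there for any to pass. Libraries of one number in the titles showed no joint deviation by correlation (0.0332 and -0.0967 within lines, from -0.161 to 0.141 across them). Their peaks did differ in width. Medians in replicates 1 and 2 were 172 and 219 bp in HC800a8-1 control and 148 and 179.5 bp in HC800a8-1 DOX libraries. In HC569a8-18 they were 176 and 209 bp in control and 192 and 204 bp in DOX libraries, so a batch by number stays possible. With replicate number as a block, 2 of 16 assignments reached the 159 gained regions (permutation p = 0.125) and the 49 lost regions had a permutation p of 0.25. Under the block the redundant tags, the peaks per 1000 tags kept and the 3 lists of unadjusted p 0.0286 had a permutation p of 0.125, the smallest that the block gives for a difference of means, so none could pass.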

Other observations

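The chromosome tests, and the choice of regions that part the lines, were made after the results were seen.

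The peak lists of the cell lines differed whatever the treatment, where a region missing from a list was only below the authors' cutoff there. Lrrk2, a kinase gene, had 3 regions listed in all 4 HC800a8-1 and no HC569a8-18 libraries, at 91672918, 91690690 and 91703159 on chromosome 15, the last at 16.8 ± 5.41 times the background (SD, n = 4). Alk, a receptor tyrosine kinase gene, had 2 such regions inside the gene, as did the synaptic genes Nrxn3 and Dlg2. In the reverse direction, Shroom3, a gene of epithelial cell shape, had 2 regions in all HC569a8-18 and no HC800a8-1 libraries (chromosome 5, 92745808 to 92746184 and 92763612 to 92763945; 14.2 ± 1.12 and 10.7 ± 1.14, SD, n = 4), and Naaladl2 had 2. In all, 145 regions were in HC800a8-1 only and 98 in HC569a8-18 only, or 108 and 145 with lists of equal length. As deposited, 4 other of the 35 splits of the libraries had a side larger than 145, up to 868 for the 4 longest lists, whereas at equal lengths the highest other split was that of DOX and control at 127. Of the fixed lists, Cldn3 had a region only in HC800a8-1, and Eya1 and Tek only in HC569a8-18.

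Whole chromosomes took different shares of the peaks in the lines. With lists of equal length, chromosome 9 held 5.22% ± 0.148 of HC800a8-1 and 2.77% ± 0.205 of HC569a8-18 peaks, and chromosome 10 held 2.37% ± 0.235 and 4.59% ± 0.316 (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0409, no overlap between the lines). List length was not the whole cause, since 14 of 20 chromosomes passed after Benjamini-Hochberg adjustment at equal lengths and 15 as deposited, whereas 0 of 20 passed between DOX and control, and 0 before adjustment. A candidate explanation is chromosome copy number: over the 20 chromosomes, the line ratio of pileup at regions in all 8 lists went with the line ratio of peak share elsewhere (r = 0.974, permutation p = 1e-05, the smallest that 100000 permutations give; 0.963 without chromosomes 9 and 10). Chromosomes are not independent samples, and regional differences in chromatin between the lines stay open. Copy number was not taken into account for the regions listed in a single line.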
